A study of Mus musculus with 48 samples.

How the data were processed

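RNA was measured with GeoMx digital spatial profiling probes on frozen sections of fixed mouse brain, and the tags were sequenced on an Illumina NextSeq instrument, per the labels' protocols. Regions of interest were chosen by immunofluorescence for TMEM119 and GFAP. The titles give 24 regions with a segment of each marker, 48 segments in all. The deposited table holds 19963 rows, of which 1 is a negative control probe, and 16 columns headed with a genotype and a number. The deposited values are a signal that is never negative. The processing software, its version, probe filters and the normalization are not given in the sources used here.

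The low values showed how the signal was scaled. In each column, 19959 of 19963 rows were whole multiples of 1 step within a tolerance of 0.000001, so each column is whole probe counts times 1 factor, and dividing by the step gave the implied counts. The smallest value of a column was 9 to 66 steps, so no count model was used. The deposited column medians were equal within a genotype and differed between genotypes. Levels were therefore made comparable by taking log2(value + 1) and subtracting each column's median over targets. A log2 difference on this scale understates the change of targets near the negative probe, because the probe background was not subtracted.

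Comparisons of TMEM119-positive with GFAP-positive segments, values per region and fits within library-plate rows had been chosen before the data were examined. They could not be run, since the columns carry neither a marker nor a region number. The comparison of genotypes came from the column headings and was chosen after these were seen. The columns were taken as TMEM119-positive segments of WT, 5xFAD and 5xFAD-LynKO brain from the series' design text, and no column was matched to a single titled segment. Whether regions come from separate animals is not known, so p-values measure the spread between regions. All 16 columns entered each model, with 6, 5 and 5 columns per genotype and no covariate.

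Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean trend) on 19960 targets, with Tmem119 and Gfap left out of the counts and no filter on low values. Calls had a Benjamini-Hochberg adjusted p under 0.05. A target was above background when it exceeded 1.5 times the negative probe in at least 5 columns, which 3364 did. The 26 gene lists, 332 genes of which 330 were measured, were written before the data were examined. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. List medians were also set against 10000 random lists matched on mean level in 200 bins. These were drawn gene by gene, which leaves out the correlation within a list. Several genes stand in more than 1 list.

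The genes named follow a rule written before the data were examined, namely Tmem119, Gfap, Lyn and Tlr4, the 12 largest passing changes in each direction, and from each list up to 4 passing members with the smallest adjusted p and up to 2 abundant members that did not pass. Its condition on regions was replaced by the condition that the columns of both groups do not overlap. The text uses part of the genes so named.

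The steps were tested on simulated data with 200 changed targets above background among 19960, for each comparison. For 5xFAD against WT, 74.6% of 67 targets changed 1.5-fold and 100% of 67 changed 2-fold were recovered, with 4.69% false calls. For 5xFAD-LynKO against WT these were 77.6%, 98.5% and 4.17%, and for 5xFAD-LynKO against 5xFAD the false calls were 3.8%. A list shifted by 0.5 log2 was called in 20 of 20 simulations, with 2 calls in 500 tests of other lists. The simulation assumed targets that vary independently, which the estimated correlations do not bear out. It also multiplied the whole signal, background included, so recovery of changes near the negative probe was not tested.

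Columns of a genotype were compared as possible duplicates by a chi-square test of the implied counts, which gave 1.16 to 6.64 per degree of freedom. No column therefore copies the counts of another of its own genotype, and pairs across genotypes were not tested in this way. WT columns 5 and 6 (1.16) and 5xFAD columns 3 and 5 (1.18) lay near the 1 that count noise alone would give. Repeated sampling of a region is thus not excluded. Intervals are 95% and cover the spread between regions. The alternatives were other scalings, filters on low or background targets, subtraction of the negative probe, pseudocounts of 5 and 0.1, array weights, the heading number as a block, a neuronal covariate, leaving out WT columns 1 and 3 together and leaving out each column. Figures were drawn with matplotlib 3.10.9. No genome build is named in the sources used here, so no coordinates are given and targets carry the symbols of the deposited table.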

Results

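The series used GeoMx digital spatial profiling, which counts light-released probe tags from chosen regions of a tissue section, to measure RNA in mouse brain. The mice were wild type, 5xFAD, a transgenic line that deposits amyloid, or 5xFAD crossed with a Lyn knockout. A further group named APP was not analysed here. Lyn is a Src-family tyrosine kinase of myeloid cells, and Tlr4 is the receptor for bacterial lipopolysaccharide. The titles name 48 segments in 24 regions of interest, 24 positive for TMEM119, a microglial surface protein, and 24 positive for GFAP, the intermediate filament of astrocytes. The deposited table has 16 columns, 6 headed WT, 5 headed 5xFAD and 5 headed 5xFAD-LynKO. No heading names a marker, and the columns were taken as TMEM119-positive segments because the series describes its analysis as one of microglial expression in these genotypes. No source used here ties a region to an animal. The series describes 6 regions per brain slice, so regions of a genotype may share an animal or a slice, and every p-value below is then too small.

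Implied probe counts per column ran from 1194248 to 2548601 in the columns headed WT, from 3205406 to 4148785 in those headed 5xFAD and from 3207094 to 5793533 in those headed 5xFAD-LynKO. The median target had 55 to 118, 153 to 195 and 146 to 269 implied counts. Most targets lay near the negative control probe, which stood at 0.859 to 0.918 of the column median under WT, 0.933 to 0.957 under 5xFAD and 0.911 to 0.968 under 5xFAD-LynKO. The number of targets over 2 times the negative probe averaged 1045 ± 367 (SD, n = 6) under WT, 459.2 ± 203 (SD, n = 5) under 5xFAD and 615.8 ± 400 (SD, n = 5) under 5xFAD-LynKO, with 121 in 5xFAD-LynKO column 1. As deposited, all columns of a genotype share a median, 86.7 for WT, 159 for 5xFAD and 196 for 5xFAD-LynKO. The median log2 difference over all targets was therefore 0.88 for 5xFAD against WT, 0.30 for 5xFAD-LynKO against 5xFAD and 1.17 for 5xFAD-LynKO against WT. All levels and differences below are relative to each column's median target, on the log2(value + 1) scale. Differences given without rescaling between genotypes keep a near-equal shift for every target. A fall smaller than the shift then turns positive by construction, which does not test its direction.

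**Figure D1:**
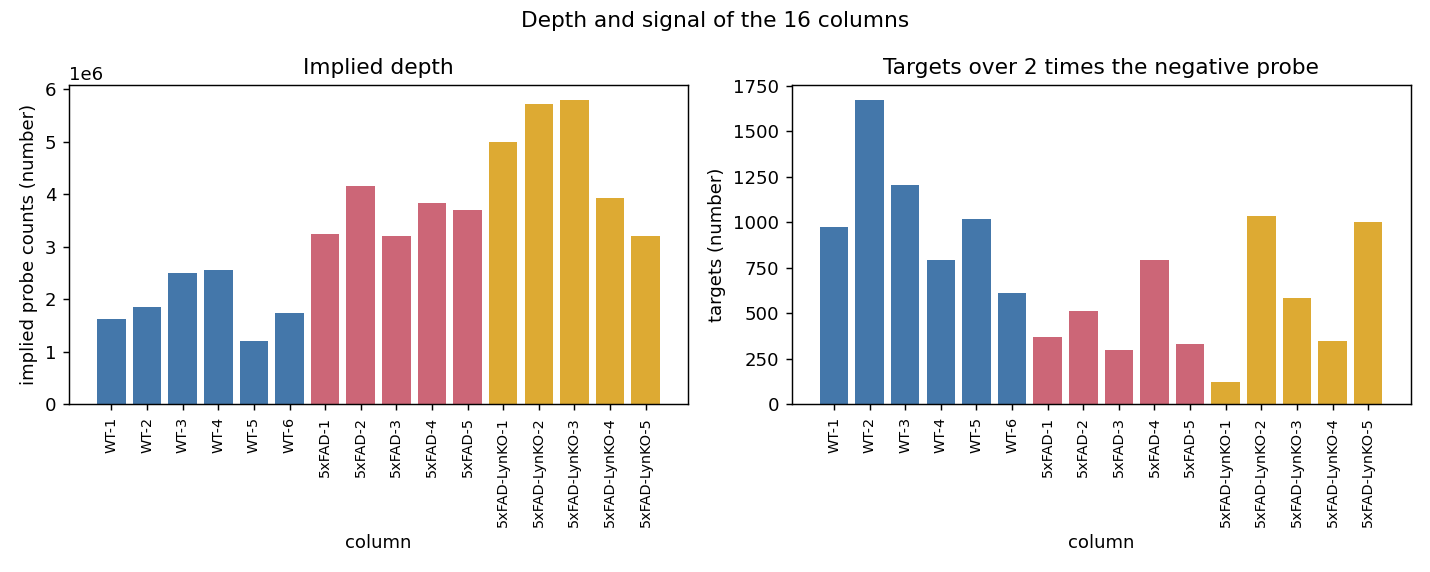
Implied probe counts (left) and number of targets over 2 times the negative probe (right) for each of the 16 columns, coloured by the genotype in the heading. The columns headed WT have the fewest implied counts, 1194248 to 2548601, and 612 to 1670 targets over 2 times the negative probe, against 298 to 793 under 5xFAD.

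The knockout's target was examined first. Lyn signal was 1.17 ± 0.14 times the column median under WT (SD, n = 6), 1.09 ± 0.057 under 5xFAD (SD, n = 5) and 1.13 ± 0.085 under 5xFAD-LynKO (SD, n = 5). Lyn in the columns headed 5xFAD-LynKO differed from that in the columns headed 5xFAD by 0.06 log2, with a 95% interval of -0.12 to 0.24 and a limma adjusted p of 0.869. The Lyn probe stood at 1.30, 1.15 and 1.21 times the negative probe in the 3 groups, under the 1.5 times taken as background, so it does not check the headings. It is also not known whether the probe lies in the deleted part of Lyn. The groups are therefore named by their column headings throughout. Tlr4 fell in the columns headed 5xFAD, from 1.21 ± 0.15 to 0.797 ± 0.13, a log2 difference of -0.60 ± 0.10 (SE, adjusted p = 0.00122). Tlr4 was 1.11 ± 0.12 under 5xFAD-LynKO, 0.48 ± 0.11 log2 above 5xFAD with an adjusted p of 0.11. Tlr4 also lay under 1.5 times the negative probe in every group, at 1.35, 0.843 and 1.18.

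The proteins used to choose segments were read as a check only. Tmem119 lay at or below the negative probe, at 0.969, 0.685 and 0.788 times it under WT, 5xFAD and 5xFAD-LynKO. Its signal was nonetheless lower in the columns headed 5xFAD than in those headed WT (-0.42 log2, limma adjusted p = 0.00468), a difference that turned positive without rescaling between genotypes, and did not pass for 5xFAD-LynKO against WT (-0.22, 0.521). Gfap was 3.52 ± 1.6 times the column median under WT, 1.17 ± 0.12 under 5xFAD and 1.22 ± 0.27 under 5xFAD-LynKO. Gfap signal differed between the groups of columns beside the microglial lists in both comparisons with WT (limma adjusted p of 0.000319 and 0.000273), but not between 5xFAD-LynKO and 5xFAD (0.04 log2, adjusted p = 0.973).

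The first comparison asked how microglial segments of 5xFAD brain differed from wild type. Of 22 genes of disease-associated microglia, 12 passed as lower and 0 as higher in the columns headed 5xFAD, but the list did not pass with an estimated correlation (camera adjusted p = 0.553). Without rescaling between genotypes 8 of the 12 turned positive, their falls being smaller than the shift of 0.88. Ctsd, the lysosomal protease cathepsin D, fell from 5.51 ± 3.0 times the column median (SD, n = 6) to 1.79 ± 0.24 (SD, n = 5), a 2.74-fold change with a log2 difference of -1.46 ± 0.24 (SE, limma adjusted p = 0.00122). Apoe, the main lipid carrier of the brain, fell from 6.41 ± 1.8 to 3.09 ± 0.94, a log2 difference of -1.06 ± 0.26 (SE, adjusted p = 0.00919). Trem2, a microglial lipid-sensing receptor, fell from 1.72 ± 0.58 to 1.05 ± 0.085, and Tyrobp, its signalling adaptor, from 1.93 ± 0.94 to 0.922 ± 0.12, with adjusted p of 0.00413 and 0.00248. WT columns 1 and 3 stood apart from the other WT columns in these genes, with Ctsd at 9.64 and 9.07 times the column median against 2.67 to 3.99, and C1qc, a complement C1q chain, at 4.62 and 4.28 against 1.79 to 1.84. With both columns left out, a setting chosen after these values were seen, the Ctsd difference was -0.99 log2 (adjusted p = 0.00437) and the Trem2 difference -0.36 (0.0165), while Apoe no longer passed (-0.82, 0.0563). Also lost were the calls of Cst3, Cplx2, Glul, C1qb, Inpp5d and Cldn11, described below, with adjusted p from 0.0625 for Cldn11 to 0.111 for Cplx2. Their differences without both columns were -0.84, -0.83, -0.73, -0.29, -0.40 and -0.42 log2 in that order. With all columns Cplx2 was also -0.83, while Cst3 was -1.17, so a lost call is not always a smaller difference. In all, 31 of the 44 named genes called, Gfap and Tmem119 included, kept their call.

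Of the 22 disease-associated microglial genes, 12 fell and 0 rose relative to the column median. When the shift of 0.88 between genotypes was left in, Trem2 and Cst7 were among those that turned positive, 4 stayed below 0 (Ctsd, Apoe, Spp1 and B2m), and the mean of the disease-associated microglia list went from -0.389 to 0.483. Adjusted over the list alone, 13 fell. Fry asks whether the genes of a list differ between genotypes in a shared direction, without comparing them with other targets. It therefore does not set aside the median difference of -0.16 log2 over all targets above background. Fry gave an adjusted p of 0.0243 for the disease-associated list. It gave 0.105 for the pan-microglial, 0.0851 for the oligodendrocyte and 0.0724 for the complement list. The other lists that passed fry were those of Alzheimer disease genes (0.0049), TLR4 and Src-family kinase signalling (0.0243), cell death and survival (0.0243), astrocytes (0.0426) and endothelial cells (0.0485). Besides Ctsd, Apoe and Trem2, the list's changes included Spp1 (osteopontin) at -0.92 log2, B2m (the light chain of MHC class I) at -0.88 and Cst7 (cystatin F) at -0.61. Trem2, Tyrobp, Spp1 and Cst7 exceeded 1.5 times the negative probe in fewer than 5 columns. The median of the list was -0.36, with a camera adjusted p of 2.26e-06 at the preset correlation and an adjusted p = 0.553 with an estimated correlation. Of 17 pan-microglial and myeloid genes, 6 fell and 0 rose, and 7 fell adjusted over the list alone. They included the complement C1q chains C1qa at -0.94, C1qb at -0.79 and C1qc at -0.99, and the lysosomal protease Ctss at -0.93, of which C1qb turned to 0.08 without rescaling. The list's camera adjusted p was 0.00802, and the adjusted p = 0.553 with an estimated correlation. The mean level of the pan-microglial list was 0.884 and 0.771 log2 in WT columns 1 and 3, but 0.182 to 0.282 in the other WT columns, which overlaps the 0.221 of 5xFAD column 5. Without WT columns 1 and 3 the list's mean difference went from -0.345 to -0.142 and did not pass (camera adjusted p = 0.0776), while the disease-associated list went to -0.243 and passed (adjusted p = 0.000266), with 4 and 6 genes called. Aif1, which encodes the microglial marker IBA1, was 1.97 ± 0.28 under WT and 1.75 ± 0.40 under 5xFAD and did not pass the test (adjusted p = 0.349). The same held for the growth factor receptor Csf1r (1.85 ± 0.64 and 1.34 ± 0.18, adjusted p = 0.0628).

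Of 14 homeostatic microglial genes, 4 fell and 1 rose, and the list did not pass (median -0.16, camera adjusted p = 0.0921). Without WT columns 1 and 3, 1 fell and the list's mean went from -0.184 to -0.028 (adjusted p = 0.861). The small GTPase gene Rhob fell by 0.66 log2, while the purinergic receptor gene P2ry12 differed by -0.08 (adjusted p = 0.669). Of 12 complement genes, 4 fell, including C4b at -0.72, and the list's adjusted p was 0.0767. Without WT columns 1 and 3, 3 fell and the list's mean went from -0.293 to -0.153 (adjusted p = 0.134). Of 23 genes of TLR4 and Src-family kinase signalling, 3 fell and 0 rose, with a list camera adjusted p of 0.353 and a fry adjusted p of 0.0243. These were Tlr4, Traf6, a ubiquitin ligase downstream of it, at -0.43, and Inpp5d, the inositol phosphatase SHIP1, at -0.37. Adjusted over the list alone, the counts of these 3 lists were the same. Without rescaling, the falls of Rhob, C4b, Tlr4, Traf6 and Inpp5d turned into positive differences. The kinase gene Fyn was 1.73 ± 0.24 under WT and 1.62 ± 0.066 under 5xFAD, with an adjusted p of 0.62.

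Genes of other cell types also differed, and without rescaling each fall named here turned into a positive difference. Of 12 oligodendrocyte genes, 4 fell and 8 fell adjusted over the list alone, with Cnp at -0.53 and Cldn11, a tight junction protein of myelin, at -0.47. The oligodendrocyte list was highest in WT columns 1 and 4 (mean log2 of 1.36 and 1.108, others 0.328 to 0.627), not in columns 1 and 3, and the other WT columns overlap the 0.246 to 0.573 of the 5xFAD columns. The list's camera adjusted p was 0.00112, and the adjusted p = 0.553 with an estimated correlation. Of 18 astrocyte genes, 2 fell, Glul (glutamine synthetase) at -0.82 and Clu (clusterin) at -0.56, and the list's adjusted p was 0.0692. The glutamate transporter gene Slc1a2 was 7.93 ± 1.7 and 4.77 ± 1.7 (adjusted p = 0.187). Of 21 reactive astrocyte genes, 5 rose and 2 fell, the falls being Vim at -0.46 and Serpina3n at -0.34, and the largest adjusted p of these named genes was 0.0268. Osmr, the oncostatin M receptor gene, rose by 0.32 log2 to 1.18 times the negative probe, and the list did not pass (camera adjusted p = 0.807). Of 13 pan-neuronal genes, 1 fell, the nuclear marker Rbfox3 at -0.44, while the synaptic gene Snap25 was 11.3 ± 6.9 under WT and 7.89 ± 4.6 under 5xFAD (adjusted p = 0.628), and the list's adjusted p was 0.169. Adjusted over the list alone, 2 astrocyte genes and 0 pan-neuronal genes fell, and 5 reactive astrocyte genes rose and 3 fell. Camk2a, of excitatory neurons, was 6.54 ± 3.4 and 3.50 ± 1.6 (adjusted p = 0.0877).

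Of 13 Alzheimer disease genes, 4 fell, among them Apoe, Trem2 and Clu, with a camera adjusted p of 0.00802 and an adjusted p = 0.224 with an estimated correlation. The list's median of -0.174 lay within the range of random lists matched on mean level (percentile 23.4, bound of the lowest 2.5% at -0.28). App was 9.73 ± 2.8 under WT and 6.79 ± 1.5 under 5xFAD (adjusted p = 0.626). Of 15 cell death and survival genes, 2 fell, the anti-apoptotic Bcl2l1 at -0.41 and the pro-apoptotic Bax at -0.30, and the list's adjusted p was 0.108. Adjusted over the list alone, the counts of these lists were the same. Further large falls were Cst3 (cystatin C) at -1.17, the synaptic gene Cplx2 at -0.83, the palmitoyltransferase gene Zdhhc24 at -0.81 and the immunophilin gene Fkbp1a at -0.74. Of the genes in this paragraph, Apoe and Cst3 stayed lower without rescaling, and Trem2, Clu, Bcl2l1, Bax, Cplx2, Zdhhc24 and Fkbp1a turned positive.

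**Figure D2:**
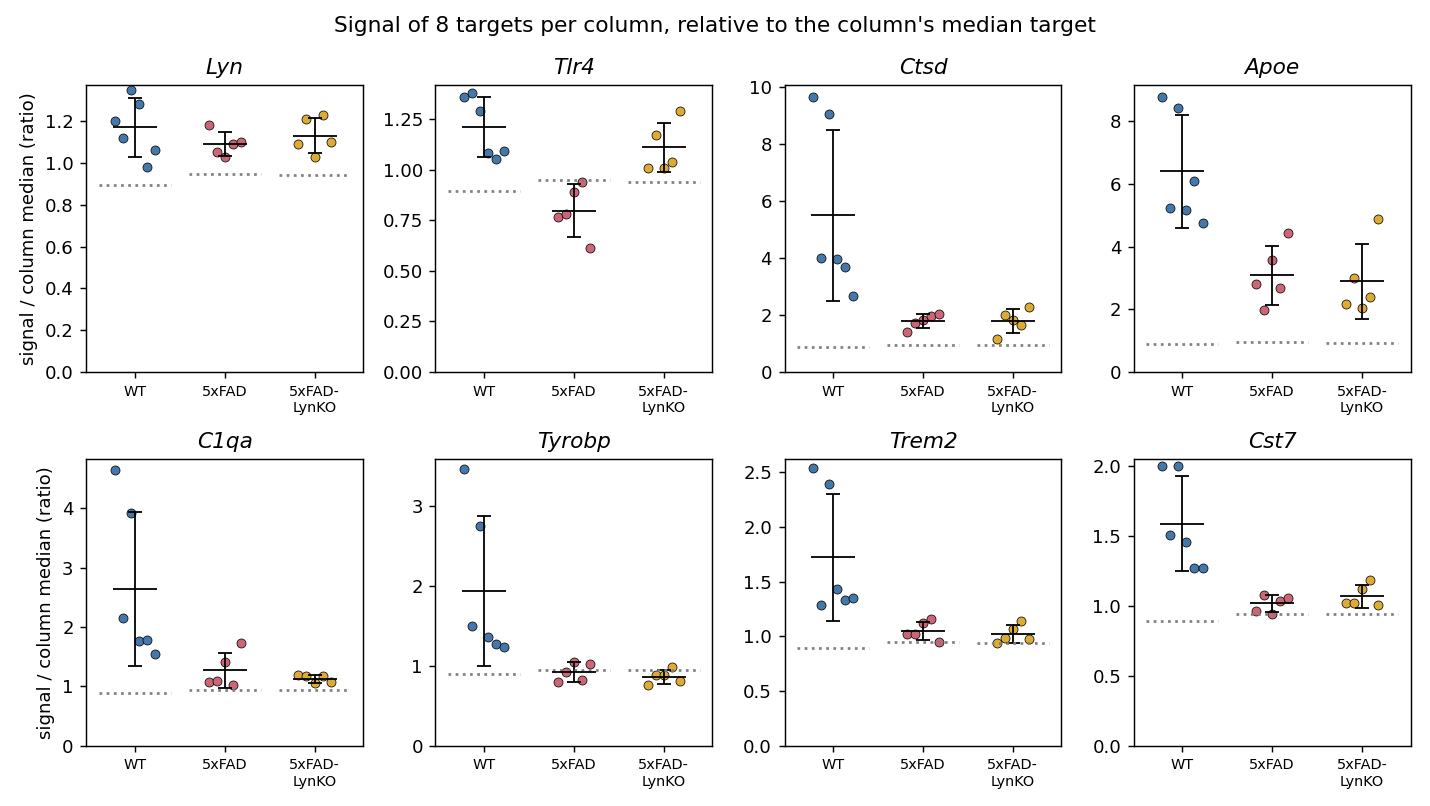
Signal of 8 targets divided by the median target of the same column, for the 6 columns headed WT, 5 headed 5xFAD and 5 headed 5xFAD-LynKO (points), with the mean and SD (bars) and the mean level of the negative probe (dotted). Ctsd averages 5.51 under WT, 1.79 under 5xFAD and 1.78 under 5xFAD-LynKO, while Lyn averages 1.17, 1.09 and 1.13. Without rescaling, the sign of the 5xFAD difference turns for Lyn, Tlr4, Trem2 and Cst7.

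In all, 2839 of 19960 targets passed the limma test at an adjusted p under 0.05, 1196 higher and 1643 lower in the columns headed 5xFAD. Of the higher targets 14, and of the lower targets 613, were among the 3363 tested targets above background. The columns headed WT can meet this limit alone. Each had 2691 to 4762 targets over 1.5 times the negative probe, against 1374 to 2838 under 5xFAD, so the filter may partly set this split. The largest rises were at the level of the negative probe, such as Rnase11, Nobox (an oocyte transcription factor) and Olfr808 (an olfactory receptor), at 1.13, 1.13 and 0.984 times it under 5xFAD, and Podxl at 1.35. Of the 26 lists, 4 passed camera, all lower, 0 passed with an estimated correlation and 6 passed fry. The groups did not overlap for 1005 targets, 5.04% of those tested, where chance gives 0.433%. The split between directions depended on the scaling, with 42.1% of calls higher on the column median, 60% on the upper quartile and 14.4% on the negative probe. Leaving out 5xFAD column 3 or 5 lowered the calls to 1414 or 1395.

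The second comparison asked what loss of Lyn changed in 5xFAD brain. Disease-associated and complement genes had close means in both groups of columns. Ctsd was 1.79 ± 0.24 under 5xFAD (SD, n = 5) and 1.78 ± 0.42 under 5xFAD-LynKO (SD, n = 5), a log2 difference of -0.03 with a 95% interval of -0.55 to 0.49 and a limma adjusted p of 0.988. Apoe was 3.09 ± 0.94 and 2.90 ± 1.2 (interval -0.67 to 0.44), and Trem2 was 1.05 ± 0.085 and 1.02 ± 0.082 (interval -0.34 to 0.25). C1qb was 1.38 ± 0.19 and 1.27 ± 0.072, and Aif1 was 1.75 ± 0.40 and 1.80 ± 0.24, with adjusted p of 0.918 and 0.933. Of the 26 fixed lists, 0 passed camera and 0 passed fry. The oligodendrocyte list stood at a median of 0.19 log2 (camera adjusted p = 0.19). The pan-microglial list stood at -0.11, with 14 of 17 genes below 0 (camera adjusted p = 0.288, and 0.888 with an estimated correlation). Its median lay at percentile 0.03 of the matched random lists, which leave out its estimated correlation of 0.33. The immediate early (0.2) and homeostatic (1.52) lists were also low and the oligodendrocyte list high (100). The pan-microglial list passed camera among targets above background (adjusted p = 0.0299) and without WT columns 1 and 3 (0.0489). Leaving out these columns kept its mean at -0.089, as no WT column enters this difference, so that pass adds no support. Snap25 was 7.89 ± 4.6 and 8.29 ± 6.1, and App was 6.79 ± 1.5 and 8.14 ± 2.6.

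By limma, 0 of 19960 targets passed, with a smallest adjusted p of 0.0715 and 2255 targets at an unadjusted p under 0.05. The groups did not overlap for 537 targets, 2.69% of those tested against 0.794% by chance. Calls appeared with array weights (643), quantile normalization (183), the negative-probe level subtracted (103) and the pan-neuronal level as a covariate (31), and leaving out 5xFAD column 4 gave 129. In simulated data of this comparison over 19960 targets, 70.1% of 67 targets changed 1.5-fold and 95.5% of 67 changed 2-fold were recovered. The changed targets were all above background, with the whole signal multiplied and independent noise. These shares therefore do not apply to targets near the negative probe, where most lay.

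The third comparison set the columns headed 5xFAD-LynKO against those headed WT, which the first comparison also used. Some genes of disease-associated microglia and complement were lower than under WT, 4 of 22 and 3 of 12, and neither list passed with an estimated correlation. Ctsd fell from 5.51 ± 3.0 times the column median (SD, n = 6) to 1.78 ± 0.42 (SD, n = 5), a log2 difference of -1.48 ± 0.24 (SE, limma adjusted p = 0.0136). C1qc fell by 1.11 log2, Ctss by 1.10, C1qa by 1.08, Tyrobp by 1.03, Spp1 by 0.79, C4b by 0.71, Trem2 by 0.69 and Cst7 by 0.53, with adjusted p from 0.0181 for C1qc to 0.0454 for Trem2. These 8 differences, and those of Mt1 and Gm21783, turned positive when the shift of 1.17 between genotypes was left in, and the Ctsd difference stayed negative. Mt1, a metal-binding metallothionein, fell by 0.63, and the predicted gene Gm21783 fell by 1.02 (adjusted p = 8.06e-07), while Dzip1l, a ciliary protein gene, rose by 0.37 to 1.07 times the negative probe. Apoe was 6.41 ± 1.8 under WT and 2.90 ± 1.2 under 5xFAD-LynKO, with an adjusted p of 0.128.

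In all, 12 targets passed, 1 higher and 11 lower, against 1761 at an unadjusted p under 0.05. Of the 26 lists 8 passed camera, all lower, and 1 passed fry. In the disease-associated list 4 of 22 genes fell (12 adjusted over the list alone), in the pan-microglial list 4 of 17 (7 alone), in the homeostatic list 0 of 14 (4 alone) and in the complement list 3 of 12 (4 alone). Their camera adjusted p were 2.99e-12, 2.6e-11, 1.6e-05 and 0.000727, and the adjusted p were 0.098, 0.098, 0.233 and 0.233 with an estimated correlation. The oligodendrocyte, astrocyte and pan-neuronal lists also passed, with 0 genes called in each, at adjusted p of 0.00122, 0.00969 and 0.0124, and 0.404, 0.251 and 0.576 with an estimated correlation. The medians of the astrocyte (percentile 6.15), pan-neuronal (9.8) and complement (4.53) lists lay within the range of random lists matched on mean level. Those of the oligodendrocyte list (0.04) and of the disease-associated, pan-microglial and homeostatic lists (0 each) lay below it. The Alzheimer disease list passed both ways, at 3.58e-05 and an adjusted p = 0.0206 with an estimated correlation, with 1 gene called and 4 alone. Its median of -0.096 nonetheless lay within the range of random lists matched on mean level (percentile 34, bound of the lowest 2.5% at -0.158). Leaving out 5xFAD-LynKO column 1 or 3 left 1 call, Gm21783, and leaving out WT column 1 or 3 left 5. Without both of these WT columns 7 were left, and of the genes named above C1qa, Spp1, Trem2, Cst7 and Dzip1l no longer passed (adjusted p from 0.0596 for C1qa to 0.373 for Cst7). Their log2 differences were then -0.66, -0.52, -0.40, -0.355 and 0.38 in that order. With all columns they were -1.08, -0.79, -0.69, -0.53 and 0.37, so that of Dzip1l did not shrink.

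All 11 targets lower in the third comparison were also lower in the first, and the 1 higher target was higher in both. Lists of these sizes drawn independently would share 0.905 and 0.0599, which leaves out the shared WT columns, and 20 simulations without any effect shared 0 in each direction, which leaves out the effects. With the WT columns split 3 and 3, so that no column served both comparisons, a median of 1.5 targets over 20 splits was lower in the third comparison and of 1 in both, so too few calls are left to judge the overlap. The log2 differences of both comparisons correlated across targets with r = 0.772, and with r = 0.453 in simulated data without any effect, because the WT columns are shared. The covariance was 0.0192 against 0.0047 in the simulation. With the WT columns split 3 and 3 over 20 splits, r averaged 0.422 and the covariance 0.0131. No WT column is shared in a split, so the simulated values are no standard for it, and no simulation was run for it. Targets are not independent replicates, so the correlations and covariances describe these columns only.

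**Figure D3:**
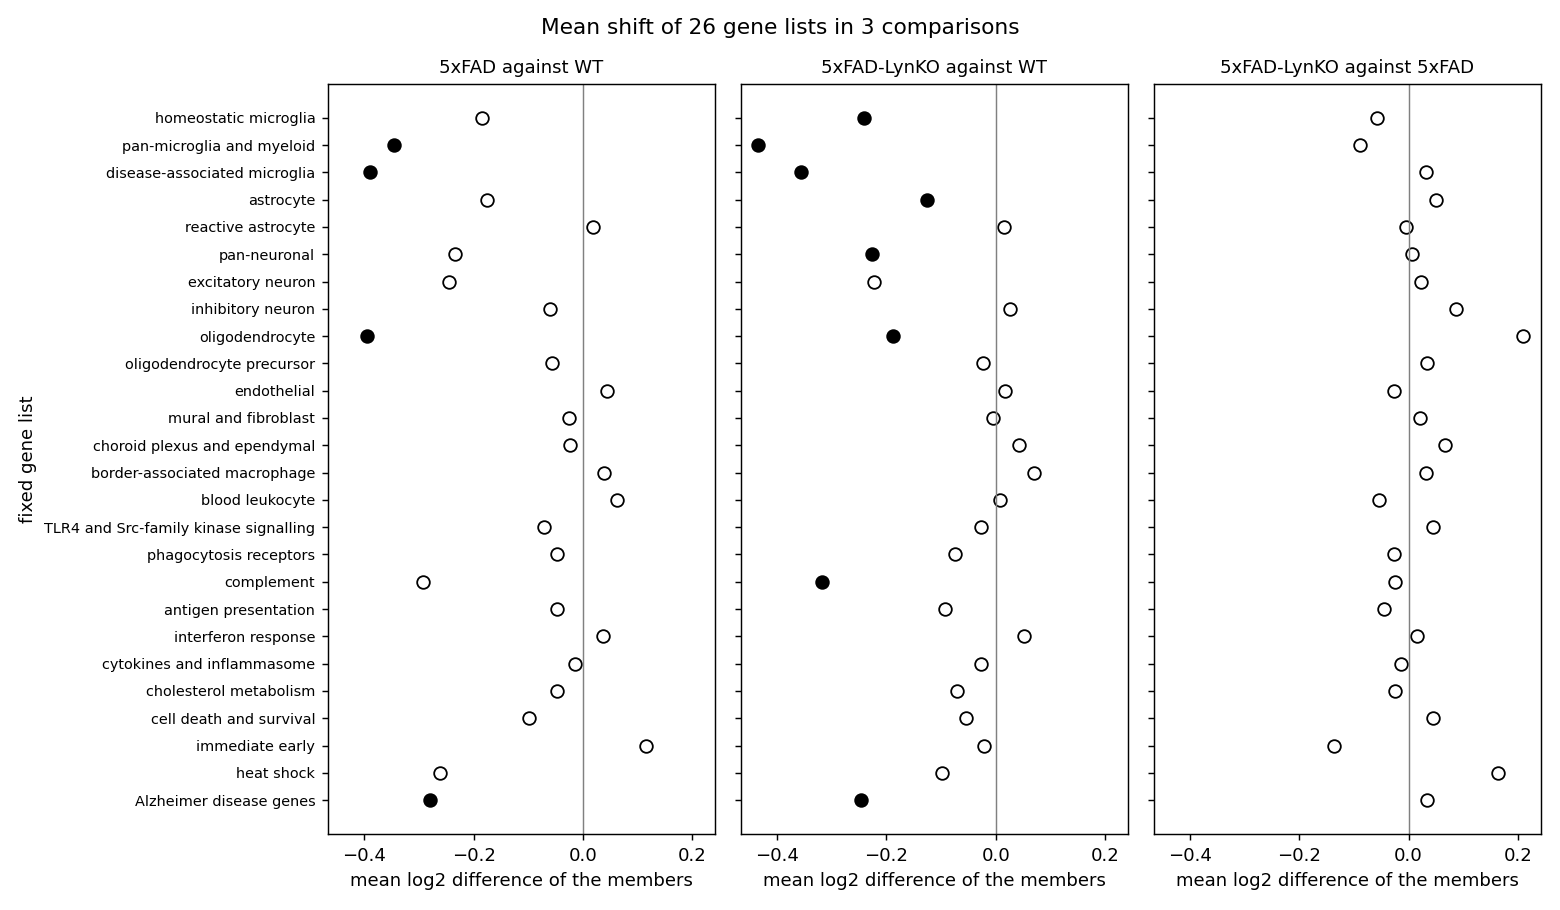
Mean log2 difference of the measured members of 26 gene lists, relative to the column median, in each of 3 comparisons. Filled points passed camera at the preset correlation with an adjusted p under 0.05, which 4, 8 and 0 lists did for 5xFAD against WT, 5xFAD-LynKO against WT and 5xFAD-LynKO against 5xFAD (0, 1 and 0 with an estimated correlation); the disease-associated microglial list lies at -0.39, -0.36 and 0.03. Without rescaling between genotypes every list mean is raised by the shift of all targets.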

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

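All of these outlier tests were run on genes and lists chosen for the text after the results were seen. In each, a single column lay far from the others of its genotype, by Dixon's test at the 95% level. Of 255 groups tested 9 stood out, fewer than the 12.8 that chance would give, and no explanation was tested.

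Relative to the column median, 5xFAD-LynKO column 1 was low for Fkbp1a (0.55 log2, others 1.15 to 1.26) and Casp1 (-0.12, others 0.0231 to 0.0783) and high for Cldn11 (0.68, others 0.058 to 0.18) and Rnase11 (0.064, others -0.34 to -0.26). It also had the highest mean of the border-associated macrophage list in its group (-0.12). In the columns headed 5xFAD, column 2 was high for Cldn11 (0.32, others -0.16 to -0.019) and column 4 for Bcl2l1 (0.65, others 0.36 to 0.39). The homeostatic microglial list was lowest in 5xFAD-LynKO column 5 (-0.034, others 0.098 to 0.14). The border-associated macrophage list was highest in WT column 6 (-0.18, others -0.29 to -0.25).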

How the results depend on the processing

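All alternatives here were chosen after the data were examined, because the planned comparisons of segments, plate rows and values per region, with their alternatives, were not run. A background limit of mean plus SD over negative probes was not run either, as the table has 1 such probe. Outside the deposited scale, 0 differences of named genes that passed in the main fit or in the alternative reversed. Signs of differences that passed in neither were not counted, such as P2ry12 for 5xFAD against WT and Lyn for 5xFAD-LynKO against WT, which turned without WT columns 1 and 3. Of the 44 named genes called for 5xFAD against WT (Gfap and Tmem119 included), 27 kept their call in every rescaled alternative that tested them and 29 with each column left out. For 5xFAD-LynKO against WT these were 2 and 2 of 13, Gfap included. Most targets lie near the negative probe, which limits any statement on them.

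With values as deposited, the targets called were 19825 for 5xFAD against WT, 15003 for 5xFAD-LynKO against 5xFAD and 19928 for 5xFAD-LynKO against WT, since all targets shift. The reversals listed here follow from this shift and do not test the direction of a difference. For 5xFAD against WT the list means turned from -0.389 to 0.483 for disease-associated microglia and from -0.345 to 0.526 for pan-microglia, and for 5xFAD-LynKO against WT from -0.356 to 0.812 and from -0.434 to 0.734. Homeostatic microglia came to 0.69 and 0.24 in the first and second pair and pan-microglia to 0.21 in the second, which passed camera as lower than other targets, whose median shift was 0.88 and 0.30. Reversed for 5xFAD against WT were Tmem119 (0.45), Lyn (0.78), Tlr4 (0.27), Cplx2 (0.045), Glul (0.055), Zdhhc24 (0.067), Fkbp1a (0.13), C1qb (0.077), C4b (0.15), Trem2 (0.23), Cst7 (0.26), Rhob (0.22), P2ry12 (0.79), Aif1 (0.69), Csf1r (0.46), Cnp (0.34), Cldn11 (0.40), Clu (0.31), Vim (0.41), Serpina3n (0.53), Rbfox3 (0.43), Traf6 (0.44), Inpp5d (0.50), Bcl2l1 (0.46), Bax (0.57), Tgfb1 (0.40), Casp1 (0.61), Ccr2 (0.62) and Fyn (0.79). Reversed for 5xFAD-LynKO against 5xFAD was Fyn (0.25). Reversed for 5xFAD-LynKO against WT were Tmem119 (0.95), Lyn (1.13), Tlr4 (1.04), C1qc (0.061), Ctss (0.071), C1qa (0.092), Tyrobp (0.14), Gm21783 (0.15), Spp1 (0.38), C4b (0.46), Trem2 (0.48), Mt1 (0.54), Cst7 (0.63), Aif1 (1.04) and Csf1r (0.65).

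The 2839 calls for 5xFAD against WT became 1396 among targets over the median level, 596 above background and 431 with the negative probe subtracted, where fewer targets were tested. The 0 calls for 5xFAD-LynKO against 5xFAD became 183 with quantile normalization, 103 with the negative probe subtracted, 643 with array weights and 31 with the neuronal covariate. The 12 calls for 5xFAD-LynKO against WT became 6 with quantile normalization, 4 above background and 3 with the negative probe subtracted. For 5xFAD against WT the pan-microglial list no longer passed above background (mean -0.61) or with the probe subtracted (-1.07), and the homeostatic list passed with the neuronal covariate (-0.17). The pan-microglial list passed above background for 5xFAD-LynKO against 5xFAD (-0.11). The cause of these changes was not tested.

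Without WT columns 1 and 3 together, calls were 1635 for 5xFAD against WT, 1 for 5xFAD-LynKO against 5xFAD and 7 for 5xFAD-LynKO against WT. The pan-microglial list no longer passed for 5xFAD against WT (-0.14), and the homeostatic list no longer passed for 5xFAD-LynKO against WT (-0.085). The pan-microglial list passed for 5xFAD-LynKO against 5xFAD (-0.089), though its mean there was the same with all columns. Of the named genes called, 31 of 44 and 8 of 13 kept their call and 0 reversed.

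Leaving out 1 column gave 1395 to 3813 calls for 5xFAD against WT, with 1624, 1414 and 1395 without 5xFAD columns 2, 3 and 5. It gave 0 to 129 for 5xFAD-LynKO against 5xFAD, 129 without 5xFAD column 4 and 2 without WT column 1. It gave 1 to 15 for 5xFAD-LynKO against WT, 1 without 5xFAD-LynKO column 1 or 3 and 5 without any other 5xFAD-LynKO column or WT column 1 or 3. For 5xFAD against WT, the homeostatic list ran from -0.24 to -0.12 and passed without WT column 2 or 6 or 5xFAD column 5, and the pan-microglial list ran from -0.39 to -0.25 and missed without 5xFAD column 4 (-0.32).

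The heading numbers do not pair the columns. Deviations of columns with the same number correlated between -0.362 and 0.452 over 15 pairs, and 2 of 16 columns correlated best with their own number. With the number as a replicate block, calls were 2615, 0 and 16, and the homeostatic list passed for 5xFAD against WT (-0.24).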

Other observations

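The tests of signal range, microglial share, exchanged headings and scaling constants, and the fits without WT columns 1 and 3, were chosen after the results were seen, and the others in this part before their results were seen.

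Several immune and activity genes not described above differed in both directions between the columns headed 5xFAD and WT, all but S100a9 at under 1.5 times the negative probe. Npas4, a neuronal activity-dependent transcription factor, rose by 0.49 log2 to 1.31 times the negative probe (limma adjusted p = 0.00242), though the immediate early list did not pass (camera adjusted p = 0.269). The cytokine gene Tnf rose by 0.34 to 0.993 times the negative probe, Pf4, of border macrophages and platelets, by 0.27 to 0.885 times, and S100a9 and S100a8, of neutrophils, by 0.29 to 1.70 times and by 0.31 to 0.892 times. In the same lists, the cytokine gene Tgfb1 fell by 0.48 to 0.606 times the negative probe, the inflammasome protease gene Casp1 by 0.27 to 0.967 times and the monocyte chemokine receptor gene Ccr2 by 0.25 to 0.909 times, and these 3 falls turned positive without rescaling. None of these 8 genes passed in the columns headed 5xFAD-LynKO against WT, with adjusted p from 0.491 for Tgfb1 to 0.856 for Ccr2, and a difference between comparisons was not tested for them. Without WT columns 1 and 3, only Npas4 and Tgfb1 of these still passed for 5xFAD against WT, and the adjusted p of the others ran from 0.0594 for Ccr2 to 0.151 for Tnf. The log2 differences were then 0.24 for Tnf, 0.24 for Pf4, 0.27 for S100a9 and 0.26 for S100a8. They were -0.25 for Casp1 and -0.24 for Ccr2, close to those with all columns. The lists of interferon response (median -0.02, camera adjusted p = 0.87), antigen presentation (-0.015, 0.886), cholesterol metabolism (0.016, 0.681), phagocytosis receptors (0.001, 0.705) and heat shock (-0.31, 0.108) did not pass for 5xFAD against WT. P-values over regions are too small where regions share an animal.

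Some disease-associated genes (12 of 22 for 5xFAD, 4 of 22 for 5xFAD-LynKO) and some complement genes (4 and 3 of 12) were lower than in the columns headed WT, against the usual rise of such genes around amyloid. With an estimated correlation neither list passed in either comparison (disease-associated camera adjusted p = 0.553 and 0.098), and the complement list did not pass at the preset one for 5xFAD against WT (0.0767). A smaller range of signal over background stays open as a cause. The disease-associated median was -0.36 for 5xFAD against WT, and the lowest 2.5% of matched random lists began at -0.13. The matched lists were drawn gene by gene, while the genes of this list had an estimated correlation of 0.32. Their range is therefore too narrow to decide. The complement median was -0.055 against a bound of -0.125, and the members went both ways. The pan-microglial median of -0.13 also lay within its range (percentile 5.89), while the homeostatic median of -0.156 and the oligodendrocyte median of -0.329 lay below their bounds of -0.137 and -0.226, so the disease-associated list is not alone in this. WT columns 1 and 3 held the highest levels, and without them the disease-associated mean was -0.24 in place of -0.39, so they carry part of the difference. A larger share of microglia in the columns headed WT cannot be told apart from a change in their state, since 8 disease-associated and 3 homeostatic genes above background averaged -0.66 and -0.53 log2 (difference -0.13, exact permutation p = 0.361 over 462 splits). Exchanged headings may also be a cause. Lyn could show only an exchange with the columns headed 5xFAD-LynKO, and lay too near the negative probe to decide. WT and 5xFAD mice both carry Lyn, so its difference of -0.093 log2 between them could not show an exchange of these headings. A true effect of genotype, the region sampled and a difference between single animals or slices stay open and untested.

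Another pattern is the 1196 targets higher under 5xFAD, nearly all at background level. Scaling to the negative probe left 497 higher calls and scaling to the upper quartile gave 1797. Each scaling moves all targets alike, so these counts do not decide whether centring on the median target is a cause, which stays open. The lower depth of the columns headed WT was examined only for the shift that count noise gives the mean log2. That shift was 0.0069 log2 for these targets, against their median of 0.33, so it is too small to give the rises. With 55 to 118 implied counts of the median target under WT, a large shift could not arise. Other ways in which depth could act were not tested and stay open.

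As deposited, 15003 targets differed between the columns headed 5xFAD-LynKO and 5xFAD. The median difference over all targets was 0.30 log2 and 0 calls were left after centring, so a different scaling constant for each genotype is a candidate source of nearly all of them. Whether total RNA per region also differed was not tested.

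Other splits of the columns were drawn 100 times for each comparison, the real one included. For 5xFAD against WT, 1 of 100 splits, the real one, gave 2839 calls, and the highest other gave 252, so a chance split of these regions can be excluded but not a difference between animals. For 5xFAD-LynKO against WT, 3 of 100 gave 12 calls or more, under the share of 0.05 set for it. The highest other gave 174, several times the real count, so a chance split is not excluded. A structure of the columns other than the headings also stays open, and no test addressed it. For 5xFAD-LynKO against 5xFAD the real count was 0, which all 100 of 100 splits reach by construction, so the splits say nothing on chance there. The highest other gave 304.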
